A study of Mus musculus with 12 samples.

How the data were processed

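Prostate tissue of 6 wild-type and 6 null libraries was sequenced after poly-A selection, with Illumina TruSeq libraries on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Cufflinks 2.0.2, DESeq and the genome build mm9, with no roles. The deposited values were on a log2 scale, from 1.07 to 21.6, and the values themselves have the form of variance-stabilised expression; the exact transformation is not given in the sources used here. Undetected genes scattered around a floor, with a median of 2.85 and a 95th percentile of 3.51 over 1123 olfactory receptor genes. No counts or depths were part of the table, so no count test could be used and the depth is unknown.

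Tests had been designed before the data were examined for counts or linear normalised values. Since the values were already on a log2 scale, they were tested as deposited with limma 3.58.1 in R 4.3.3 with mean-variance trend and robust moderation, Benjamini-Hochberg adjustment and a threshold of 0.05, and no pseudocount was added. The planned minimum of 1 would have kept all genes, so genes were kept at a value of at least 4 in at least 6 libraries, a level chosen after seeing the floor. A repeat without any filter is among the alternatives. Genotype was the only term, and all 12 libraries entered.

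The libraries were divided into 2 sets of 3 within each genotype. Sets were found as the split of 6 libraries into triplets in which a library lay nearest to the equal mix of the others, over genes with a mean of at least 10. This was the third definition tried after the data were seen: a division by eye gave the same sets, and complete-linkage clustering of correlations, tried in between, put null library 2 with libraries 3, 4 and 6. A second fit on the 4 set means, also chosen after seeing the data, gives the second set of counts. Its calls under the clustered sets are among the alternatives.

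The 25 gene lists with 340 members, of which 320 were tested, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Of 25 lists, 6 passed with camera at the preset correlation, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 7 over set means. Lists said to pass or not did so with camera unless fry is named. Fry, which sets no list against the other genes, passed more lists over 12 libraries. It was not run over set means, so its p-values take the libraries of a set as independent. Among them were urothelium (fry adjusted p = 6.51e-06), oxidative phosphorylation (fry adjusted p = 0.0173) and proliferation (fry adjusted p = 0.0327), which camera did not pass. The text names Ehmt2, Uty and Hoxb13, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 and no overlap between genotypes, and up to 4 called members of each list by adjusted p (with under 2 called, the 2 members of highest mean). The mean of at least 5 had been meant for linear values and was applied on the log2 scale. Some items that the rule names, the level of the targeted gene and a planned comparison by gene position are not reported here, while counts over all genes and lists include every tested gene.

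The fits were tested on simulated data in 10 runs over 15096 genes, with the spread within and between sets taken from the libraries and 200 genes changed. Changes of 0.5, 1 and 2 were recovered in 74.9%, 94.5% and 98.9% of cases over 12 libraries and in 0%, 27.6% and 68.5% over set means. Alternatives were quantile normalization, upper quartile scaling, limma without trend, an exact rank-sum test, no filter, a filter at 5, a test against a 1.5-fold change and each library left out. Added after seeing the data were the set means, a random block per set, each set left out, null libraries 5 and 6 left out and a residual component as covariate.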

Results

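Whole prostate tissue from 4-month-old mice was profiled by poly-A selected RNA sequencing, with 6 libraries from wild-type mice and 6 from mice homozygous for a null allele, called null below. The animals were of a hybrid background of 2 inbred strains. The deposited table held 23284 genes on a log2 scale, of which 15096 were tested. Read totals were not part of the table, so the depth of each library is unknown. The 10 highest genes held 20.9% to 26.0% of the sum of the values taken back to the linear scale. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

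The libraries of each genotype were divided into 2 sets of 3. Wild-type libraries 1 to 3 and 4 to 6 formed the sets of that genotype, and null libraries 1, 2 and 5 and null libraries 3, 4 and 6 formed those of the other. Over 3633 genes with a mean of at least 10, the median spread between wild-type libraries was 0.0835 within a set and 0.156 across sets. Between null libraries it was 0.0959 within a set (0.0767 to 0.162) and 0.173 across sets (0.137 to 0.230), so these ranges overlapped. Null libraries 1 and 2 of the same set lay 0.162 apart, with 263 genes at least 2-fold apart, and null libraries 1 and 3 of different sets lay 0.137 apart, with 230. The null sets rest on libraries 5 and 6, which lay nearest to equal mixes of 1 with 2 and of 3 with 4, and not on libraries 1 and 2 being alike. Between genotypes the median spread was 0.335. Because libraries of a set may not be independent, counts of called genes are given over all 12 libraries and over the 4 set means, 2 against 2. Genes named as risen or fallen were called over 12 libraries, and those that did not pass over set means are named or belong to lists with a count of 0 there. Camera results are over 12 libraries unless stated. A set mean hides the spread within its set, such as that between null libraries 1 and 2. For some genes it is therefore not the stricter fit. In data simulated with the spread of these sets, 7.47% of unchanged genes were called over 12 libraries and 0.0134% over set means. The simulation changed 200 of 15096 genes, far fewer than were called in these data, so these shares do not carry over directly.

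Of 15096 tested genes, 8013 (53.1%) changed over 12 libraries, 4224 higher and 3789 lower in null prostate, a balance that turned after quantile normalization (4073 and 4174) and upper quartile scaling (3892 and 4260). Over set means 2195 genes passed, 1144 higher and 1051 lower, and 2192 of them were also called over 12 libraries. At least 2-fold differences were found for 1058 genes over 12 libraries, 452 higher and 606 lower, and for 887 over set means, 390 higher and 497 lower. The median difference of all tested genes was 0.012. Counts of called list members over 12 libraries are to be read against the 53.1% of all tested genes called. A list near or under that share holds no excess of calls. Adjusting over a list alone used the same p-values and adds no separate evidence. Simulated genes with a log2 change of 1 were recovered in 94.5% of cases over 12 libraries and 27.6% over set means. Only 200 genes were changed in the simulation, so its adjusted threshold was stricter than in these data, where 2195 passed over set means. Its recovery shares are therefore not estimates for these data. Genes that missed the second threshold cannot be read as unchanged.

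Sbp, the spermine-binding protein of prostatic fluid, fell by 15.04 on the log2 scale, from 19.12 ± 0.11 (SD, n = 6) to 4.07 ± 0.64 (SD, n = 6), with adjusted p = 8.80e-13 over 12 libraries and adjusted p = 9.26e-07 over set means. Msmb, which encodes beta-microseminoprotein, fell by 5.62 and Pbsn, which encodes probasin, fell by 2.15, while Clu, which encodes the chaperone clusterin, rose by 2.07. Of 13 tested prostate secretory genes, 5 rose, 6 fell and 2 were not called, and 11 passed when adjusted over the list alone. Over set means 2 rose and 5 fell. The largest rise on the list was that of Wfdc15b, by 6.59. The list did not pass as a group with camera (camera adjusted p = 0.377), but it passed as lower with fry (fry adjusted p = 3.40e-08). Its median difference was -0.069 and its mean -1.67.

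**Figure D1:**
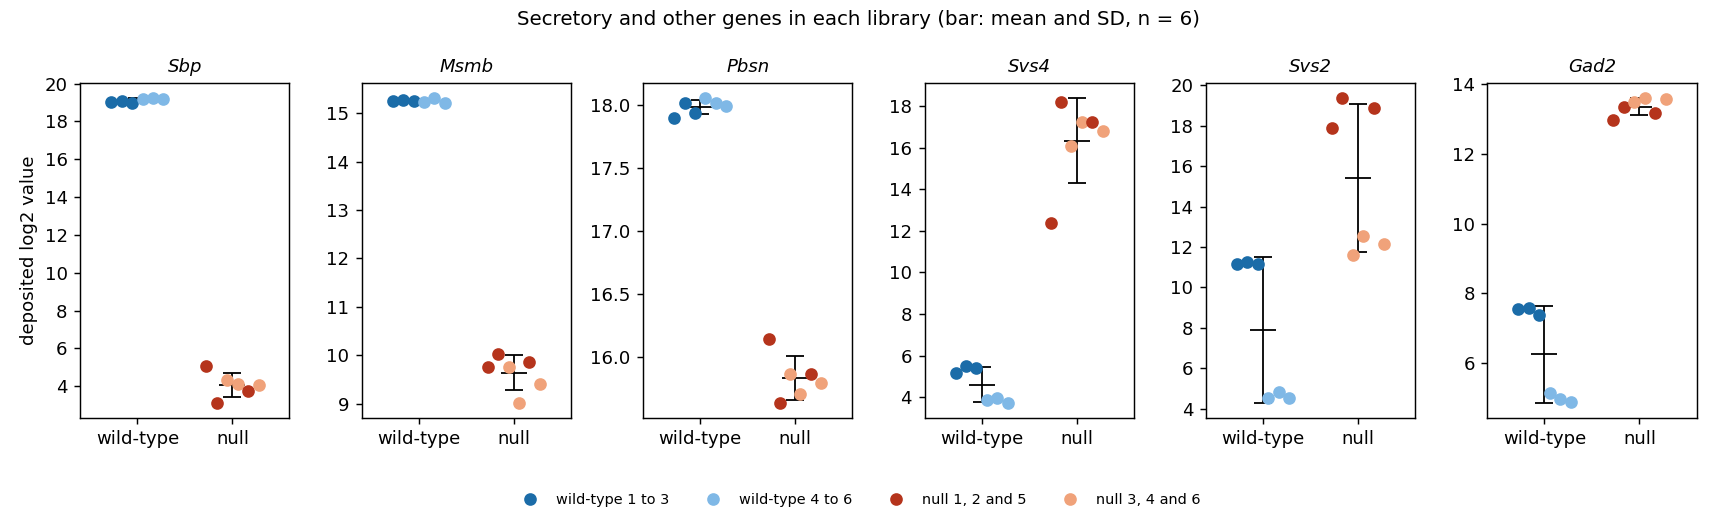
Deposited log2 values of 6 genes in each of the 12 libraries, by genotype on the x axis, with the black bar giving mean and SD and the colour giving the set of 3. Sbp, Msmb and Pbsn are lower in all null libraries, while Svs4 and Svs2 are higher and vary widely between null libraries.

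Transcripts of seminal vesicle secretory proteins were higher in null libraries. All 9 tested members rose over 12 libraries and when adjusted over the list alone, and 6 rose over set means. The set mean averages null libraries 1 and 2, where Svs4 stood at 12.38 and 18.20. Svs4 rose by 11.71 to 16.32 ± 2.05 (SD, n = 6), Svs3a by 10.28, Svs3b by 7.50 and Svs6 by 6.36. The list passed as a group (camera adjusted p = 6.23e-05; adjusted p = 0.132 with an estimated correlation). Levels varied within genotypes, and Svs2 stood at 11.2 to 11.3 in wild-type libraries 1 to 3 and 4.5 to 4.8 in libraries 4 to 6. In null libraries 1, 2 and 5 Svs2 stood at 17.9, 19.4 and 18.9, but in null libraries 3, 4 and 6 at 11.6, 12.6 and 12.1, close to wild-type libraries 1 to 3. Svs2 differed by 7.49 with adjusted p = 0.0112 over 12 libraries but adjusted p = 0.358 over set means, and Svs5 by 9.28 with adjusted p = 0.122 over set means.

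Beyond the Svs genes, the largest rises were those of Sva by 8.01, Gad2, a glutamate decarboxylase, by 7.11 and the gene model Gm4956 by 6.78. Next came Wfdc15b, a member of the prostate secretory list, by 6.59 and Ceacam10, a member of the seminal vesicle list, by 6.51. Gad2 stood at 13.36 ± 0.24 (SD, n = 6) in null libraries and at 6.25 ± 1.39 (SD, n = 6) in wild-type libraries. The largest falls after Sbp were those of Mug1 (-9.18), Abpd (-7.87), the gene model Gm4684 (-7.79), H2-Q10 (-7.17), Spink5 (-7.09), Abpb (-6.87), Crabp1 (-6.25), Pigr (-6.09) and BB123696 (-5.99). Pigr encodes the receptor that carries polymeric immunoglobulins across epithelia, Crabp1 a retinoic acid-binding protein and Spink5 a serine protease inhibitor. All of these also passed over set means. A set mean averages null libraries 1 and 2, which stood at 7.21 and 12.44 for Sva and 7.74 and 13.89 for Gm4956. For Sva the standard error was 0.785 over 12 libraries and 0.535 over set means. Passing over set means is no stricter check for such genes. Wild-type means of Svs3a, Svs3b, Svs6 and Sva, the highest 3.29 for Svs3a, lay under 3.51, the 95th percentile of undetected olfactory receptor genes, so the size and rank of their rises are limited by that floor. Several of the genes that fell ended near the level of undetected genes, such as Abpb at 2.73 ± 0.19 (SD, n = 6), so the size of their fall is limited in the same way. Paralogs such as Svs3a and Svs3b share sequence, and how reads were divided between them is not given in the sources used here.

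The series title names G9a, a histone H3K9 methyltransferase encoded by Ehmt2, and UTY, a Y-linked relative of the H3K27 demethylase Kdm6a. Uty fell by 0.80 (adjusted p = 6.51e-07 over 12 libraries; adjusted p = 0.0141 over set means). Ehmt2 stood at 11.75 ± 0.094 (SD, n = 6) in wild-type and 11.66 ± 0.030 (SD, n = 6) in null libraries, a difference of -0.10 that did not pass (adjusted p = 0.0943; adjusted p = 0.576 over set means). The call of Ehmt2 depended on scaling, with a difference of -0.22 and adjusted p = 0.000154 after quantile normalization. Without wild-type replicate 2 its difference was -0.13 with adjusted p = 0.0230, and without wild-type libraries 4 to 6 it was -0.019 with adjusted p = 0.761. Hoxb13, a homeobox gene of the HoxB cluster, fell by 0.62 (adjusted p = 3.85e-06; adjusted p = 0.0355 over set means).

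**Figure D2:**
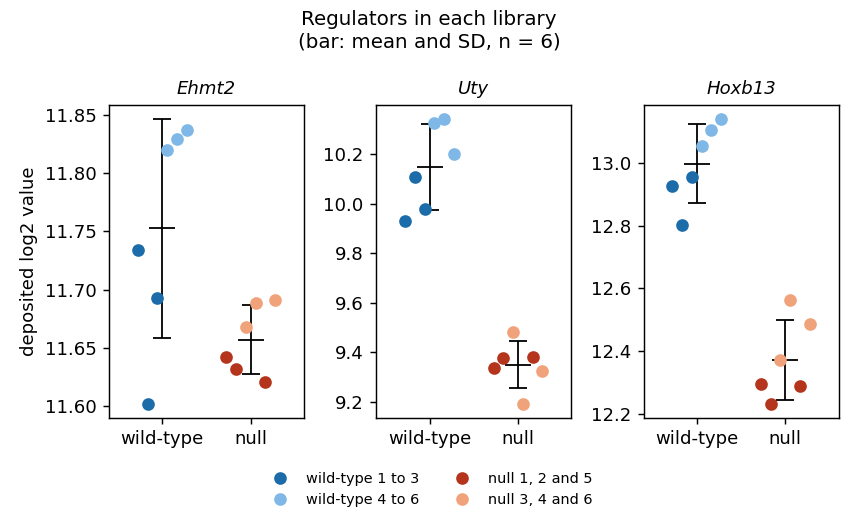
Deposited log2 values of Ehmt2, Uty and Hoxb13 in each of the 12 libraries, by genotype on the x axis, with the black bar giving mean and SD and the colour giving the set of 3. The y axes differ between genes, and Uty differs by -0.80 between group means while Ehmt2 differs by -0.10.

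Among 22 regulators of histone H3K9 and H3K27 methylation, 13 rose, 4 fell and 5 were not called, with 17 called when adjusted over the list alone, and 4 rose and 1 fell over set means. Cbx5, which encodes heterochromatin protein HP1 alpha, rose by 1.05, the demethylase gene Kdm6b rose by 0.55 and Kdm6a rose by 0.43. As a group the list did not pass with camera (camera adjusted p = 0.0516), but it passed as higher with fry (fry adjusted p = 6.38e-06). Of 4 Y-linked genes, Uty and Ddx3y fell, the latter by 0.88, and 2 were not called. Both passed when adjusted over the list alone, and over set means Uty passed and Ddx3y did not (adjusted p = 0.0742; camera adjusted p = 0.190).

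Basal epithelial and developmental genes were higher in null prostate. Of 11 basal markers, 8 rose, 2 fell and 1 was not called, with 11 called when adjusted over the list alone and 4 higher over set means. Trp63, the basal transcription factor p63, rose by 1.16, Col17a1 by 1.12, Dsc3 by 1.14 and the keratin gene Krt17 by 1.10 (camera adjusted p = 0.0174; adjusted p = 0.645 with an estimated correlation). Of 17 prostate development regulators, 12 rose, 1 fell and 4 were not called, with 13 called when adjusted over the list alone. Over set means 5 rose and 1 fell. Notch1 rose from 9.63 to 10.63 and Sox9 by 0.46, while Hoxb13 was the member that fell (camera adjusted p = 0.00744; adjusted p = 0.132 with an estimated correlation).

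Luminal and androgen-responsive genes moved both ways. All 10 luminal markers were called, over all genes and when adjusted over the list alone, with 6 higher and 4 lower, and over set means 1 rose and 1 fell. Cd24a fell by 0.80, and Prom1 rose by 0.80, Dpp4 by 0.66 and Krt19 by 0.45 (camera adjusted p = 0.746). Over set means Dpp4 (adjusted p = 0.0567) and Krt19 (adjusted p = 0.0768) did not pass. Of 17 androgen-responsive genes, 5 rose, 7 fell and 5 were not called, with 12 called when adjusted over the list alone, and 3 rose and 4 fell over set means. The kinase gene Sgk1 rose by 1.78, Zbtb16 by 1.01 and Acsl3 by 0.58, and Fkbp5 fell by 0.73. The list did not pass with camera (camera adjusted p = 0.718), and its median of -0.052 and camera direction were negative. With fry it passed in the opposite direction, as higher (fry adjusted p = 0.0488).

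Immune cell and interferon genes were lower in null prostate. All 12 myeloid genes fell, also when adjusted over the list alone, with 1 lower over set means. C1qb fell by 1.38 and C1qc by 1.26, both subunits of complement C1q, and Cd68 fell by 0.77 and Csf1r by 0.75 (camera adjusted p = 0.000289; adjusted p = 0.645 with an estimated correlation). Over set means C1qb (adjusted p = 0.0554), Cd68 (adjusted p = 0.0707) and Csf1r (adjusted p = 0.0540) did not pass. The wild-type sets also stood apart in each named myeloid gene. C1qb stood at 10.07 to 10.08 in wild-type libraries 1 to 3 and at 9.06 to 9.23 in libraries 4 to 6. In null libraries C1qb stood at 8.00 to 8.60. Of 12 lymphocyte genes, 9 fell and 3 were not called, the same number when adjusted over the list alone, with 2 lower over set means. The B cell genes Ms4a1 (-1.90), Cd79a (-1.93) and Cd79b (-1.93) fell (camera adjusted p = 0.00606, and adjusted p = 0.699 with an estimated correlation). Cd79b did not pass over set means (adjusted p = 0.0644). The wild-type sets stood apart in these genes too, with Cd79a at 6.42 to 6.58 in libraries 1 to 3 and 4.94 to 5.32 in libraries 4 to 6. In null libraries Cd79a stood at 3.56 to 4.29, near the 3.51 of undetected genes, which limits the size of its fall. Of 14 interferon response genes, 11 fell, 1 rose and 2 were not called, with 14 called when adjusted over the list alone, and 6 fell and 1 rose over set means. Oas1a fell by 1.31, Usp18 by 1.08 and Stat2 by 0.37, and Mx1 rose by 1.44 (camera adjusted p = 0.000585; adjusted p = 0.205 with an estimated correlation). Stat2 did not pass over set means (adjusted p = 0.0512).

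**Figure D3:**
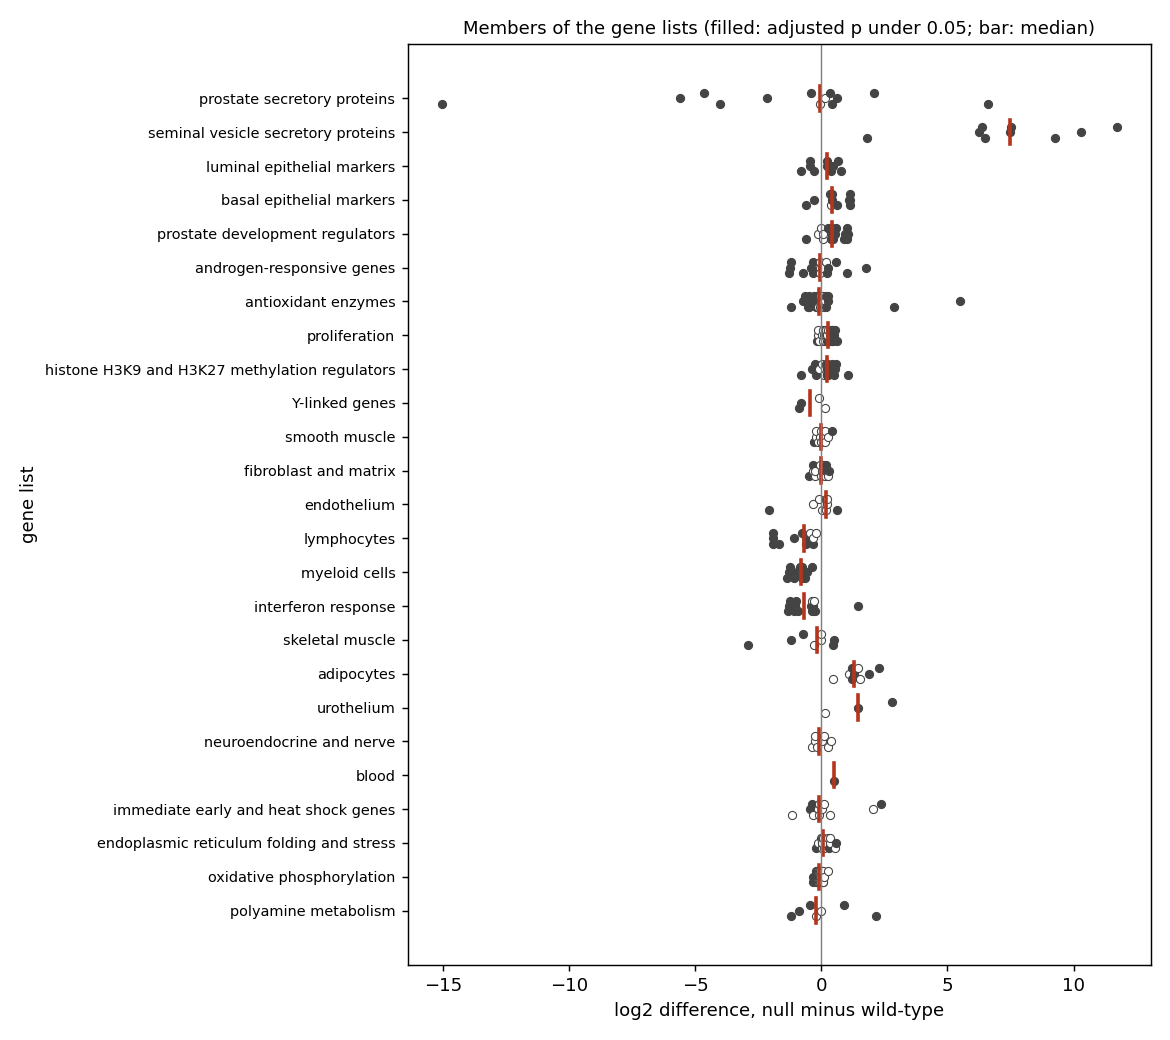
Log2 difference (null minus wild-type, x axis) of each tested member of the 25 gene lists (y axis), with filled points for members called over 12 libraries and a red bar for the list median. Seminal vesicle genes have a median of 7.49, and the myeloid and lymphocyte lists have medians of -0.81 and -0.69.

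Stromal lists changed little over 12 libraries, but the smooth muscle list was called higher without null libraries 3, 4 and 6 (camera adjusted p = 0.0370). Of 12 smooth muscle genes, Synpo2 rose by 0.43 and Myl9 fell by 0.29, and 10 were not called. Of 14 fibroblast and matrix genes, 3 rose and 2 fell, among them Mgp by 0.30, Col6a1 by 0.20, Fbln1 by -0.50 and Dcn by -0.32. Of 10 endothelial genes, Flt1 rose by 0.62 and Emcn, which encodes endomucin, fell by 2.07, with 8 not called. Adjusted over the list alone, 2, 5 and 2 members passed, and over set means 0, 0 and 1 by limma, the last being Emcn. At an unadjusted p under 0.05, 0 smooth muscle and 1 fibroblast member passed over set means. Camera adjusted p was 0.954 for smooth muscle and 0.986 for the other two. Median and mean differed in sign in all of these lists, at -0.021 and 0.013 for smooth muscle, 0.0070 and -0.039 for fibroblasts, and 0.17 and -0.085 for endothelium.

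Markers of neighbouring tissues varied. Of 9 adipocyte genes 5 rose and 4 were not called, with 5 called when adjusted over the list alone. Over set means 3 were higher, including Lep, which was not called over 12 libraries (limma adjusted p = 0.151, and 0.0381 over set means). Car3 rose by 2.27, Plin1 by 1.31, Retn by 1.21 and Pck1 by 1.21, with a camera adjusted p of 0.0950 over 12 libraries and 0.00191 over set means (adjusted p = 0.736 over 12 libraries with an estimated correlation). Car3 (adjusted p = 0.114) and Plin1 (adjusted p = 0.0568) did not pass over set means. The genotypes overlapped in all 4 of these genes, because null library 2 stood at 5.57 for Car3, 3.31 for Plin1, 3.50 for Retn and 3.74 for Pck1. Null library 1 stood at 10.09 for Car3, and a set mean averages null libraries 1, 2 and 5, which hides this spread. For Retn the standard error was 0.363 over 12 libraries and 0.206 over set means. The smaller camera p over set means is therefore not a stricter result. Wild-type libraries 1 to 3 stood at 7.03 to 7.39 for Car3. Of 3 urothelial genes, Upk2 rose by 2.81 and Upk1b by 1.44, with 3 called when adjusted over the list alone and 2 higher over set means (camera adjusted p = 0.0786). Of 8 skeletal muscle genes 2 rose, 3 fell and 3 were not called, with 5 called when adjusted over the list alone and 2 lower over set means (camera adjusted p = 0.439). Myh1 fell by 2.90, Myh2 by 1.21 and Actn3 by 0.73, and Acta1 rose by 0.45, and over set means Actn3 (adjusted p = 0.115) and Acta1 (adjusted p = 0.0842) did not pass. None of 8 neuroendocrine and nerve genes was called by limma over all genes, adjusted over the list alone or over set means, and 0 had an unadjusted p under 0.05 in either fit. The camera adjusted p of that list was 0.986. Alas2, the 1 blood gene tested, rose by 0.52, also when adjusted over the list alone and over set means.

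Of 26 genes on the antioxidant enzyme list, 6 rose, 12 fell and 8 were not called, with 18 called when adjusted over the list alone. Over set means 2 rose and 4 fell. Qsox1 rose by 5.51, and as a sulfhydryl oxidase it is an antioxidant enzyme only by the list as fixed. Gpx3, an extracellular glutathione peroxidase, rose by 2.88, while Prdx6 fell by 0.65 and Txnrd1 by 0.51. The list did not pass with camera (camera adjusted p = 0.276), but it passed as lower with fry (fry adjusted p = 0.000684). Its median was -0.093 and its mean, which includes Qsox1, was 0.14. Of 7 polyamine genes, 2 rose, 3 fell and 2 were not called, with 5 called when adjusted over the list alone and over set means. Azin1, the antizyme inhibitor, rose by 2.17 and Smox by 0.90, and Sms, spermine synthase, fell by 1.19 and Odc1, ornithine decarboxylase, by 0.88. The list did not pass with camera (camera adjusted p = 0.567), but it passed as lower with fry (fry adjusted p = 0.0327). Its median was -0.19 and its mean 0.049.

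Of 28 proliferation genes, 12 rose, 1 fell and 15 were not called, with 11 called when adjusted over the list alone and 0 over set means (2 at an unadjusted p under 0.05). Mki67 rose by 0.63, Kif11 by 0.56, Cdk1 by 0.45 and Mcm4 by 0.33 (camera adjusted p = 0.0950). Of 24 oxidative phosphorylation genes, 8 fell and 16 were not called, with 8 called when adjusted over the list alone and 0 over set means (2 at an unadjusted p under 0.05). Cox7a2 fell by 0.34, Cox5b by 0.33, Sdhd by 0.21 and Sdha by 0.15 (camera adjusted p = 0.118). Of 17 endoplasmic reticulum genes, Pdia4 and Sdf2l1 rose by 0.56 and 0.31 and Sec61b fell by 0.22, with 14 not called, 3 called when adjusted over the list alone and 0 over set means, where 1 had an unadjusted p under 0.05 (camera adjusted p = 0.628). Of 12 immediate early and heat shock genes, Hspa1b rose by 2.35, Junb fell by 0.38 and Nr4a1 by 0.44, and 9 were not called. Of the 12, 1 passed when adjusted over the list alone and 0 over set means, where 1 had an unadjusted p under 0.05 (camera adjusted p = 0.775; median -0.10, mean 0.19). Hspa1b stood at 12.60, 13.36 and 13.00 in null libraries 1, 2 and 5 but at 9.71, 8.85 and 9.26 in null libraries 3, 4 and 6, against 9.07 to 9.19 in wild-type libraries 1 to 3 and 8.22 to 8.63 in wild-type libraries 4 to 6 (adjusted p = 0.422 over set means). Svs2 was also highest in null libraries 1, 2 and 5.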

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

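Over 97 named genes, 10 of 194 gene and genotype groups held a library far from the other 5, which is 5.15%. Chance flags about 1 in 20 groups where libraries and genes are independent. Libraries of a set may not be independent, and flags gathered in 1 library, so the shares cannot be compared. Among the 10 flags were 7 values of null library 1. It was lowest in 6 genes: Svs4 at 12.38, Svs3a at 10.04, Sva at 7.21, Svs3b at 7.10, Gm4956 at 7.74 and Wfdc15b at 7.98. In the B cell gene Ms4a1 it was highest, at 4.90. The others were Svs3b in wild-type library 2 at 2.72, Notch1 in wild-type library 5 at 9.76 and Dsc3 in null library 3 at 5.64.

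All tests of this paragraph and the next were chosen after the result was seen. Null library 5 lay between null libraries 1 and 2 in 98.9% of 263 genes at least 2-fold apart between them, and null library 6 between 3 and 4 in 97.1% of 68 genes. The highest share among the other 58 of 60 triples was 83.4%. Around the equal mix the spread was 0.0427 and 0.0434, and at least 0.0762 in any other triple, so libraries 5 and 6 may hold pooled RNA or reads of the others. Of 73 genes that parted the wild-type libraries sharply, 97.3% parted libraries 1 to 3 from 4 to 6, which is consistent with repeats of 1 RNA in each set, while shared cages, litters or dissections stay open and untested. Of 50 genes that parted the null libraries sharply, 34 parted libraries 1, 2 and 5 from the rest and 12 parted library 1 alone. Repeats of 1 RNA are argued against for null libraries 1 and 2, with 263 genes at least 2-fold apart against at most 5 within a wild-type set. Null libraries 3 and 4, with 68 such genes, also passed the bound set against repeats, over 5 times the most within a wild-type set. Repeats stay open for them only by a rule added last, which left open a pair whose spread met the bound for repeats. The count of genes replaced a first test by spread. Its bounds were 1.5 times the spread of wild-type sets for repeats and 2 times against them. Libraries 3 and 4 met the bound for repeats at 1.49, and libraries 1 and 2 fell between at 1.94.

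Seminal vesicle transcripts varied between null libraries 1 to 4 over a log2 range of 5.82 for Svs4 and 7.74 for Svs2. Carry-over of 1 tissue with fixed transcript ratios would keep the log2 ratio of any pair of members constant, but the median range over 36 pairs was 5.37, and 4.76 over the 28 pairs without the weakly expressed Spinkl. Ranges under 1 were found for 5 pairs, Svs3a with Svs3b (0.415), Svs2 with Pate4 (0.448), Svs6 with Ceacam10 (0.822), and Svs4 with Svs3a (0.863) and Svs3b (0.870). Among Svs3a, Svs3b, Svs4, Svs6 and Ceacam10 the ranges of all pairs lay between 0.415 and 2.33. Fixed ratios are argued against for the list as a whole, but stay open among these genes and for Svs2 with Pate4. The tissue that brings Svs4 is also argued against as the source of most of the other 443 called genes at least 2-fold higher in null, since 68.9% of them had a range under 1, as had 66.9% of 456 such genes called or not. For the 138 called genes with a range of at least 1 it stays open, and 11 of them, Sva, Gm4956 and Wfdc15b included, took the order of Svs4 over null libraries 1 to 4. Of the 305 with a range under 1, 5 took that order. Carry-over in differing parts, and expression by the null prostate itself, stay open and could not be separated in bulk tissue.

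The 8013 changed genes were the most in 100 drawn splits of the 12 libraries out of 462, with 1 split as large, the real one. The splits take single libraries as independent, which those of a set may not be. Splits that mix the genotypes also hold the genotype difference within each group, which lowers their counts. They therefore cannot exclude chance. The highest other split called 433 genes, and it followed the sets, joining wild-type libraries 1 to 3 with null libraries 1, 2 and 5. With sets kept whole there are 3 pairings, too few for a share under 0.05; the real one, the 1 as large, gave 2195 genes over set means and the highest other 0.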

How the results depend on the processing

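Of 8013 changed genes (4224 higher, 3789 lower), a test against a 1.5-fold change left 1056 (487 and 569). The balance turned under both scalings, with 4073 higher and 4174 lower after quantile normalization and 3892 and 4260 after upper quartile scaling. The next settings were chosen after seeing the data. Set means gave 2195 (1144 and 1051), set means with clustered sets 3020 (1637 and 1383), wild-type set means against 6 null libraries 4880 (2619 and 2261) or against null libraries 1 to 4 3232 (1759 and 1473), and a random block per set 4984 (2682 and 2302). Leaving out each of the 12 libraries gave 7586 to 7887 genes, and each set of 3 gave 6827 to 7848. Ehmt2 passed after quantile normalization (-0.22), upper quartile scaling (-0.13), a residual component (-0.10) and without wild-type libraries 1 to 3 (-0.17), but without wild-type libraries 4 to 6 it stood at -0.019 (adjusted p = 0.761); with single libraries left out it ranged from -0.13 (passing only without wild-type replicate 2) to -0.079. Against 1.5-fold, Uty (-0.80, adjusted p = 0.0845) and Hoxb13 (-0.62) no longer passed. Gene lists past the threshold numbered 6, with 0 under an estimated correlation and 11 without null libraries 1, 2 and 5. The smooth muscle list, not called over 12 libraries, was called higher without null libraries 3, 4 and 6, with a median of 0.26 there against -0.021; the cause was not tested for any of these. Over set means 66 of 102 named genes kept their call and 36 lost it. Neither scaling moved the median of all genes by over 0.1. The pseudocount of 0.1 had no meaning on log2 values, and the surrogate variable was not run. Depth is unknown, so what it limits could not be assessed.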

Other observations

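Genes were grouped by the letters that open their symbols, into 262 families of at least 8 tested members. At least 2-fold calls made up 7.01% of tested genes, and 4 families differed from that share by Fisher's exact test after adjustment. Of 32 Cyp genes, 4 were higher and 5 lower (adjusted p = 0.0221), and of 15 Mfsd genes 3 were higher and 3 lower (adjusted p = 0.0221). Of 10 genes opening with Ms, 0 were higher and 5 lower (adjusted p = 0.0221). Zfp genes were called less often, with 7 of 342 (2.05%; adjusted p = 0.0152). Members of such families can share reads.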
